A study of Mus musculus with 36 samples.

How the data were processed

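Total RNA of C57BL/6 mice given PBS, DMOG or roxadustat was sequenced after ribosomal RNA depletion with a stranded kit (RNeasy extraction, TruSeq with Ribo-Zero Gold). The 36 libraries are 6 per treatment for each of 2 tissue labels, liver and retina, with 1 table per label. The values are FPKM per the file headers and the deposited processing notes, which name bcl2fastq 1.8.3, TopHat2 (version 2), Cuffdiff 2.2.1 and the mouse build mm9. How the authors scaled the libraries and which annotation they used is not stated. Each library has its own column, so replicates were not pooled. The labels do not say whether replicates are separate animals, whether libraries with the same number share an animal, or which dose and time were used, so p-values measure the spread between these libraries.

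Each table lists 22558 genes, of which 25 carry spreadsheet dates in place of symbols and were kept under those names. A row of totals in the table labelled retina was left out. In the table labelled liver 3323 genes, and in that labelled retina 4260 genes, were at 0 in every library. Libraries labelled liver summed to 542785 to 617853 FPKM with 16991 to 17424 genes above 0, and those labelled retina to 433021 to 540324 FPKM with 16029 to 16389 genes above 0. No library pair was identical (correlations of 0.953 to 0.994 and of 0.937 to 0.992). The transcriptomes are those of the other tissue, so groups follow the labels, both labels and transcriptomes are named, and the lists of a tissue were tested on the libraries that hold its transcriptome, a choice made after the data were examined. The reference annotation is of another build and was used for no value.

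The files give no read counts, so depth is unknown and no counting intervals or floors are given. Low values of a library are multiples of a common step, which gives a relative depth per library. It was 0.852 ± 0.0227 (SD) for PBS, 1.08 ± 0.139 for DMOG and 1.05 ± 0.152 for roxadustat in the libraries labelled liver, and 1.02 ± 0.0673, 0.987 ± 0.145 and 0.972 ± 0.162 in those labelled retina. Histone and crystallin genes have close paralogs, so the level of a single member is uncertain.

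Genes with a mean of at least 0.5 FPKM over the 18 libraries of a table were tested, 13779 labelled liver and 12657 labelled retina, as log2(FPKM + 0.5), a scale that understates changes of genes near the pseudocount. Each table was fitted as 3 group means in limma 3.58.1 (with statmod 1.5.0, R 4.3.3), with empirical Bayes and a mean trend, 15 residual degrees of freedom, two-sided tests and Benjamini-Hochberg adjustment over all genes tested at 0.05. The comparisons were DMOG with PBS, roxadustat with PBS and roxadustat with DMOG in each label, and the difference of each drug's response between the labels (labelled liver minus labelled retina) over 11101 genes that pass the filter in both, fitted over all 36 libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

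The genes to name were set by a rule: up to 10 highest and 10 lowest log2 fold changes per comparison with PBS, and 5 and 5 in other comparisons, among called genes with a mean of at least 1 FPKM in a group and, within a label, every treated library on the same side. Small and unnamed RNAs were passed over. Egln1, Egln2, Egln3, Hif1an, Hif1a, Epas1, Vegfa and Epo were always named, Epo where it passed the filter, which was in the libraries labelled retina alone. For the lists, the rule was to show the 2 to 4 members with the smallest adjusted p, and the members shown are examples from among these, with 1 or none for some lists. Some genes that these rules name are not reported here. Examples of overlapping calls were picked after their values were seen.

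Of 43 gene lists, 13 apply to both tissues, 15 to liver and 15 to retina. Lists with at least 5 members were tested with camera of limma at a preset correlation of 0.01, adjusted over the 27 lists tested per table, with an estimated correlation beside it. Of these, 13, 9 and 13 lists were called in the libraries labelled liver for DMOG, roxadustat and roxadustat against DMOG, and 13, 9 and 5 in those labelled retina. With an estimated correlation, 0, 2 and 2, and 0, 0 and 0, were called. The mean level of each of 28 lists per table was also compared between treatments by a two-sided exact permutation test over 924 assignments (smallest possible p 0.00216), chosen after the data were examined. It asks whether the mean level changed, and camera whether a list changed more than other genes. It called 0, 7 and 9 lists for the label liver, in the same order, and 12, 9 and 0 for the label retina.

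The filter, model, comparisons, naming rule, lists and alternatives were set before the data were examined, with the exceptions named here as later choices. The alternatives for the values were pseudocounts of 0.1 and 1, no filter or a mean of at least 5 FPKM, and rescaling to an equal total or by the median ratio. Those for the model were no mean trend, robust empirical Bayes, array quality weights, Xist as a covariate, a replicate block, 2 groups alone, an estimated correlation for lists, tissues fitted alone, and each library left out in turn. A lens covariate, the mean log2 level of the lens list, and a fit of roxadustat without DMOG replicate 5 were added after the data were examined.

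The fit was tested on simulated data with known changes, drawn from normal noise at the mean and spread of each gene. At log2 changes of 0.5, 1 and 2 it recovered 86.6%, 97.0% and 100% of changed genes for DMOG with PBS in the libraries labelled liver, and 61.2%, 92.5% and 98.5% in those labelled retina. For the difference of the DMOG response between labels it recovered 55.2%, 94.0% and 98.5%. False calls were 10 of 199, 3 of 171 and 16 of 181 calls.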

Results

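The libraries labelled liver carried the transcriptome of a retina, and the libraries labelled retina carried that of a liver. Over the 18 libraries labelled liver, Sag, the rod arrestin gene, had a median of 2588 FPKM (2166 to 3683), and Pde6b, a rod phosphodiesterase gene, had 637 FPKM. Apoa1, which encodes the main apolipoprotein of HDL, had a median of 0.278 FPKM there. Over the 18 libraries labelled retina, Apoa1 had a median of 9038 FPKM (6299 to 12786), Afp, the alpha-fetoprotein gene, had 6968 FPKM, and Sag had 0.163 FPKM. Alb and Mup1, abundant in adult liver, were listed at 0 in all 18. Alb had a median of 0.0369 FPKM with the label liver, so it was measured there. Why both were 0 is unknown, and no age is given. Each of the 36 libraries had a higher mean level for the gene lists of the other tissue than for those of its labelled tissue. Every result is therefore named by the label with the transcriptome beside it.

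**Figure D1:**
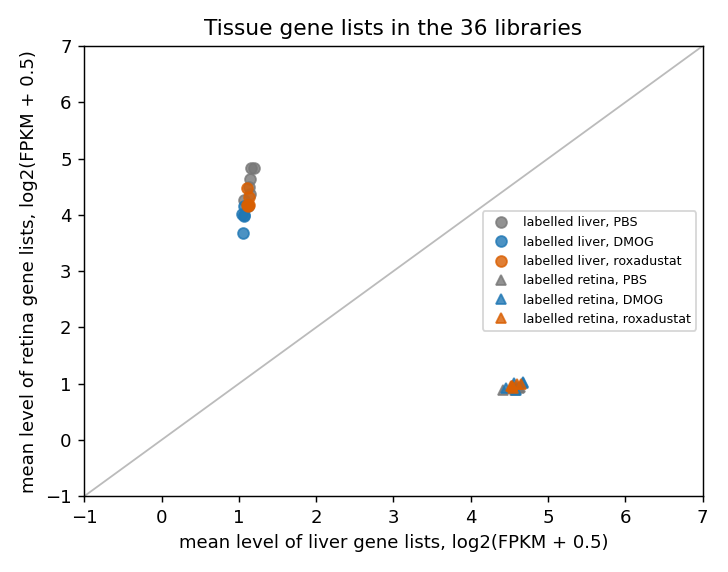
Mean log2(FPKM + 0.5) of the liver gene lists (x axis) and of the retina gene lists (y axis) in each of the 36 libraries, 1 point per library, by tissue label. All 18 libraries labelled liver are higher for the retina lists, and all 18 labelled retina are higher for the liver lists.

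The question behind the treatments is whether DMOG and roxadustat, both inhibitors of the prolyl hydroxylases that mark HIF alpha subunits for degradation, act in liver, in retina or in both. Each treatment had 6 libraries per tissue label, and the labels give neither the dose nor the time of either compound. The first principal component held 34.1% of the variance of the libraries labelled liver and 39.9% of that of the libraries labelled retina. The levels of Xist and of Y-linked genes split the libraries labelled liver into 3 female and 3 male with PBS, 2 and 4 with DMOG, and 3 and 3 with roxadustat. Some of these libraries carried both signals. Roxadustat replicate 5 had Xist at 18.4 and a Y-linked sum of 4.58 FPKM, and DMOG replicate 2 had 22.2 and 2.28 FPKM. PBS replicate 6, counted as male, had Xist at 1.29 and a Y-linked sum of 77.5 FPKM. The source of the weaker signal was not tested. The libraries labelled retina split into 3 and 3 with PBS, 4 and 2 with DMOG, and 1 and 5 with roxadustat, so sex and roxadustat overlapped in part there.

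With DMOG, 29 of 36 HIF targets were higher in the libraries labelled retina (liver transcriptome). Epo, the gene of erythropoietin, was higher than the PBS mean in 5 of 6 libraries and went from 0.221 ± 0.152 FPKM with PBS to 18.2 ± 9.33 FPKM with DMOG (mean ± SD, n = 6 per group), a log2 fold change of 4.06 ± 0.70 (SE, adjusted p = 0.00117). Egln3, which encodes an oxygen-sensing prolyl hydroxylase, rose from 6.96 ± 1.24 to 49.7 ± 23.4 FPKM, a log2 fold change of 2.51 ± 0.36 (adjusted p = 0.000792). Nr0b2, which encodes the corepressor SHP, fell from 26.8 ± 5.26 to 5.19 ± 7.92 FPKM (log2 fold change -3.01 ± 0.45, adjusted p = 0.000792). In all, 2526 of 12657 genes were called, 1046 higher and 1480 lower, against 4360 at an unadjusted p under 0.05.

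DMOG replicate 5 of these libraries lay with PBS. Its Epo was listed at 0 against 21.9 ± 3.04 FPKM (SD) in the other 5 DMOG libraries, and its Egln3 was 8.23 FPKM against 58.0 ± 12.9 FPKM. Without this library, 4489 genes were called, 2194 higher and 2295 lower, and the log2 fold changes became 4.97 ± 0.19 (SE) for Epo, 2.96 ± 0.13 for Egln3 and -3.55 ± 0.23 for Nr0b2. For these 3 genes the change with all 6 libraries was smaller and its error wider than without this library. With each library rescaled to an equal total, 17.7% of 3270 called genes were higher, against 41.4% here, so the balance of higher and lower genes depended on the scaling.

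The genes ranked here were called, reached at least 1 FPKM and had every DMOG library on the same side of the PBS mean. Besides Egln3, the largest rises included those of O3far1, the gene of a fatty acid receptor (4.10 ± 0.62, adjusted p = 0.000792), Hamp, the hepcidin gene (3.64 ± 0.85, adjusted p = 0.0062), Ero1l, an oxidase of protein folding (2.59 ± 0.37), P4ha2, a collagen prolyl hydroxylase (2.44 ± 0.35), and Bnip3, a mitophagy receptor (2.39 ± 0.36). Efna1, an ephrin, rose by 2.38 ± 0.32, Tnnc1, a troponin, by 2.06 ± 0.36, Apol11b, an apolipoprotein L, by 1.99 ± 0.56 (adjusted p = 0.0184), and Fam162a, a mitochondrial protein, by 1.99 ± 0.27 on the log2 scale. Egln1, the main oxygen-sensing hydroxylase, rose by 1.18 ± 0.17 and Vegfa, the vascular growth factor, by 1.09 ± 0.19 (adjusted p = 0.00127). After Nr0b2, the largest falls among them included those of Lars2, a mitochondrial tRNA synthetase (-1.73 ± 0.40, adjusted p = 0.0058), Krt20, a keratin (-1.70 ± 0.28), Hlf, a clock output (-1.63 ± 0.22), Osgin1, a stress-induced gene (-1.49 ± 0.26), and Mid1ip1, an activator of lipid synthesis (-1.44 ± 0.21). Adck3 (-1.32 ± 0.22), Paqr7 (-1.30 ± 0.21), Acot4 (-1.27 ± 0.22) and Lrrc3 (-1.23 ± 0.20) followed. Hif1a (-0.19 ± 0.08, adjusted p = 0.104) and Epas1 (-0.20 ± 0.12, adjusted p = 0.248), the genes of the HIF alpha subunits, were not called, and neither were Egln2 (-0.10 ± 0.08) and Hif1an (-0.08 ± 0.05), which encode further oxygen-sensing hydroxylases. Hif1a was called lower without DMOG replicate 5 (-0.24 ± 0.08, adjusted p = 0.021), and the other 3 were not called.

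**Figure D2:**
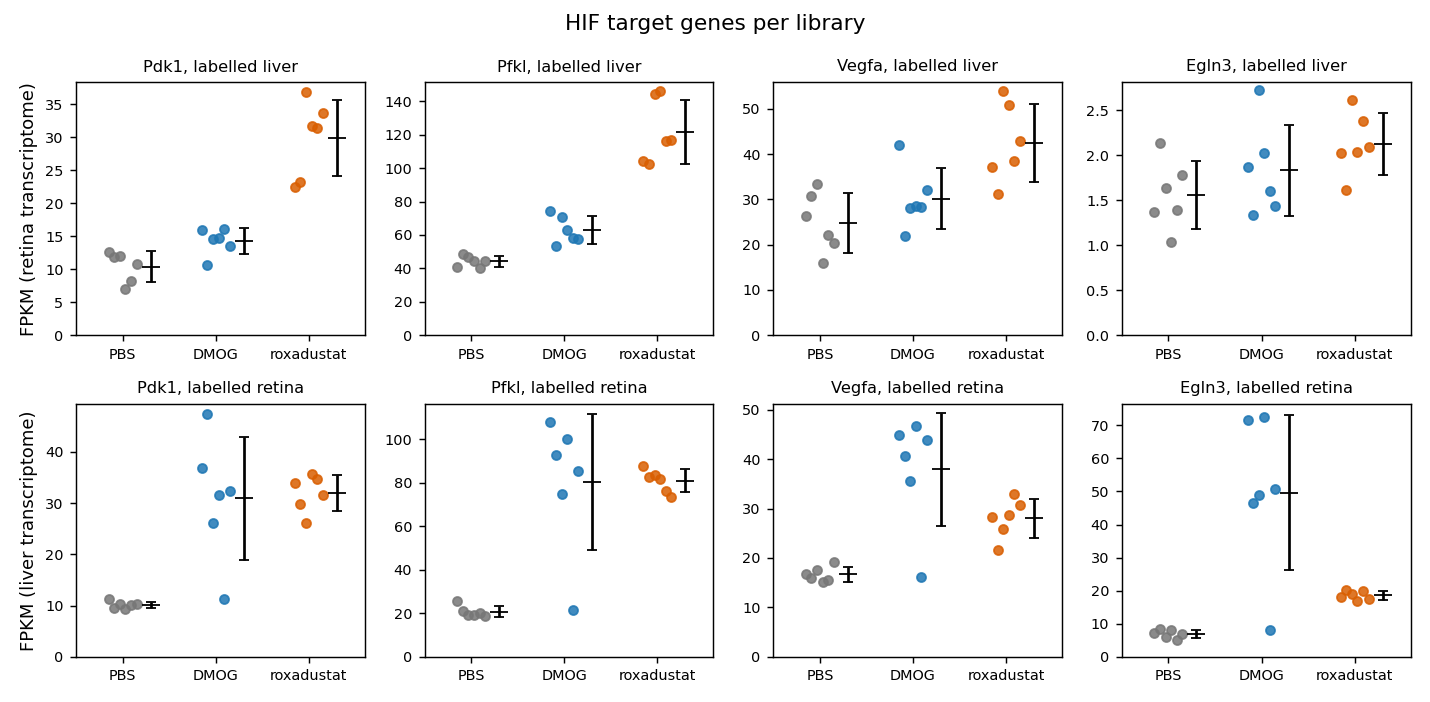
FPKM (y axis, from 0) of Pdk1, Pfkl, Vegfa and Egln3 in each library by treatment (x axis) and tissue label, 1 point per library, with mean ± SD beside the points (n = 6 per group). In the libraries labelled retina (liver transcriptome), DMOG replicate 5 lies with the PBS libraries.

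Of the 36 HIF targets tested with DMOG in the libraries labelled retina (liver transcriptome), 29 were higher, none was lower and the rest were not called, against 31 higher adjusted over the list alone (adjusted p = 0.430 with an estimated correlation). Egln1, Egln3, P4ha2 and Bnip3 had the smallest adjusted p. Of 20 glycolysis genes, 17 were higher (18 adjusted over the list alone), among them Pfkl, a phosphofructokinase (1.78 ± 0.27), Pdk1, which closes off pyruvate oxidation (1.44 ± 0.22), and Pgk1, a kinase of glycolysis (1.43 ± 0.21), with an adjusted p of 0.430 with an estimated correlation. By exact permutation with all 6 libraries, HIF targets (difference 1.24, adjusted p = 0.026) and glycolysis (1.12, 0.0337) were called. Without DMOG replicate 5, the HIF targets gave 31 higher and an adjusted p of 0.00893 with an estimated correlation, and glycolysis gave 18 higher and 0.058.

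The lists of metabolism called with DMOG in these libraries held higher and lower genes. Of 17 genes of gluconeogenesis and glycogen, 11 were higher, as they were adjusted over the list alone, among them Irs2, an insulin receptor substrate (1.31 ± 0.19), Gbe1, a glycogen branching enzyme (1.41 ± 0.22), and Ugp2 (0.83 ± 0.15), with an adjusted p of 0.430 with an estimated correlation. Of 20 cholesterol synthesis genes, 8 were lower, such as Srebf2, the regulator of the pathway (-0.53 ± 0.09), and Fdft1 (-0.64 ± 0.13), and 1, Insig1 (1.17 ± 0.20), was higher, against 9 and 1 adjusted over the list alone (adjusted p = 0.469 with an estimated correlation). Of 17 fatty acid synthesis genes, 5 were lower, such as Srebf1 (-0.87 ± 0.15) and Fasn (-0.81 ± 0.15), against 9 lower and 3 higher adjusted over the list alone (adjusted p = 0.462 with an estimated correlation). Of 31 genes of fatty acid oxidation and ketogenesis, 5 were lower, such as Cpt1a (-0.70 ± 0.15) and Ppara (-0.67 ± 0.17), also adjusted over the list alone (adjusted p = 0.620 with an estimated correlation). Of 10 urea cycle genes, 4 were higher, such as Nags (1.07 ± 0.19) and Arg1 (1.23 ± 0.22), also adjusted over the list alone (adjusted p = 0.469 with an estimated correlation). In the iron list of 18, 6 were higher and 1 was lower (9 and 1 adjusted over the list alone), among them Epo, Fam132b, the erythroferrone gene (1.48 ± 0.26), and, lower, Steap3 (-0.96 ± 0.18), with 0.430 by the estimated correlation. By exact permutation of the mean level, gluconeogenesis and glycogen, the urea cycle and the iron list were called (adjusted p = 0.0242 each), and cholesterol synthesis (0.0886), fatty acid synthesis (0.101) and fatty acid oxidation (0.143) were not. With DMOG replicate 5 left out, cholesterol synthesis had 12 lower genes, fatty acid oxidation 11 lower, fatty acid synthesis 9 lower and 3 higher, and the iron list 10 higher and 2 lower.

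Acute phase and immediate early genes were also called as lists with DMOG in the same libraries. Of 29 acute phase genes, 10 were higher, such as Steap4 (1.60 ± 0.33) and Socs3 (1.02 ± 0.23), and 1 was lower, against 17 and 1 adjusted over the list alone (adjusted p = 0.430 with an estimated correlation). Of 18 immediate early and glucocorticoid genes, 10 were higher, such as Dusp1, a phosphatase (1.47 ± 0.25), and Cdkn1a, a cell cycle inhibitor (1.65 ± 0.28), and 3 were lower, such as Fkbp5 (-0.89 ± 0.17), against 12 and 3 adjusted over the list alone (adjusted p = 0.430 with an estimated correlation). Of 26 angiogenic factors and receptors, 6 were higher, such as Vegfa and Apln (1.74 ± 0.33), and 1 was lower, against 7 and 3 adjusted over the list alone (adjusted p = 0.469 with an estimated correlation). Oxidative phosphorylation (29 genes, adjusted p = 0.716 with an estimated correlation) and the cell cycle (28 genes, 0.710) were called as lists without a called member. The lists not called by camera were the prolyl hydroxylase and HIF pathway (4 of 8 higher), the clock (3 of 13 higher, 7 lower) and the unfolded protein response (5 of 17 higher, 3 lower). Also not called were bile acids (5 of 17 lower), one-carbon metabolism (3 of 25 higher, 3 lower), drug metabolism (2 of 21 lower), liver endothelium (2 of 14 higher, 1 lower), bile duct cells (2 of 7 higher, 1 lower) and stellate cells (1 of 14 lower). Erythroid cells (16 genes), neutrophils (14), the interferon response (25), macrophages (14) and lymphocytes (13) had 0 called members, and of 3 exocrine pancreas genes, too few for a test, 1 was lower. The exact permutation test called the acute phase, immediate early and angiogenic lists (adjusted p = 0.0354 each), and not oxidative phosphorylation or the cell cycle (0.320 each). It also called the prolyl hydroxylase and HIF pathway and the unfolded protein response (0.0242 each) as higher, and the clock (0.026) and bile acids (0.0337) as lower. When DMOG replicate 5 was left out, 8 of 14 macrophage genes, 4 of 25 interferon genes, 4 of 28 cell cycle genes, 2 of 29 oxidative phosphorylation genes and 1 of 14 neutrophil genes were higher. The acute phase list then had 16 higher and the unfolded protein response 8 higher and 4 lower, while drug metabolism had 7 lower. Angiogenic factors had 9 higher and 3 lower, bile acids 2 higher and 7 lower, and one-carbon metabolism 4 higher and 6 lower. The macrophage list (adjusted p = 0.0108), the interferon list (0.0108) and the prolyl hydroxylase and HIF pathway (0.0286) were then called by camera at the preset correlation. With an estimated correlation they had an adjusted p of 0.506, 0.702 and 0.219 and were not called. Oxidative phosphorylation (0.220), fatty acid synthesis (0.0704) and the urea cycle (0.0696) were then not called at the preset correlation.

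With roxadustat, the libraries labelled retina (liver transcriptome) had 24 of 36 HIF targets higher and 11 of 20 cholesterol synthesis genes lower. Epo rose from 0.221 ± 0.152 FPKM with PBS to 4.77 ± 1.32 FPKM with roxadustat (mean ± SD, n = 6 per group), a log2 fold change of 2.84 ± 0.70 (SE, adjusted p = 0.0256), higher in 6 of 6 libraries. Sc4mol, a sterol oxidase, fell from 53.5 ± 12.5 to 22.5 ± 6.64 FPKM (log2 fold change -1.25 ± 0.26, adjusted p = 0.0088). In all, 530 of 12657 genes were called, 274 higher and 256 lower, against 2394 at an unadjusted p under 0.05. The fit shares its estimate of the spread with DMOG replicate 5, and without that library 1111 genes were called, 522 higher and 589 lower. With each library rescaled to an equal total, 32.3% of 752 called genes were higher, against 51.7% here. The count fell to 353 without PBS replicate 3, to 349 without PBS replicate 6 and to 344 without roxadustat replicate 1.

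Among the largest rises with roxadustat in these libraries, by the same limits, were those of O3far1 (3.89 ± 0.62, adjusted p = 0.00156), Cyp17a1, a steroid hydroxylase (2.88 ± 0.39), Adm2, a vasodilator peptide (2.67 ± 0.35), Fgf23, a phosphate hormone (2.64 ± 0.44), Ankrd37 (2.62 ± 0.61, adjusted p = 0.0191), and Crybb3, a crystallin (2.61 ± 0.47). Slc16a3, a lactate exporter, rose by 2.57 ± 0.35 and A2m, a protease inhibitor, by 2.32 ± 0.48 on the log2 scale. Egln3 rose by 1.38 ± 0.36 (adjusted p = 0.0342), Egln1 by 1.12 ± 0.17 (adjusted p = 0.00127) and Vegfa by 0.73 ± 0.19 (adjusted p = 0.0382). Among the largest falls were those of Clec2h, a lectin (-2.44 ± 0.43, adjusted p = 0.003), Lars2 (-1.72 ± 0.40, adjusted p = 0.0173), Gpr110, an adhesion receptor (-1.38 ± 0.22), and Cyp7a1, the first enzyme of bile acid synthesis (-1.25 ± 0.33, adjusted p = 0.0393). Chka (-1.17 ± 0.28), Slc34a2 (-1.14 ± 0.20), Phlda2 (-1.08 ± 0.26) and Krt20 (-1.02 ± 0.28, adjusted p = 0.0451) followed. Hif1a fell by 0.32 ± 0.08 (adjusted p = 0.0303) and Epas1 by 0.44 ± 0.12 (adjusted p = 0.0426) on the log2 scale, while Egln2 (-0.18 ± 0.08) and Hif1an (-0.01 ± 0.05) were not called.

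Of the 36 HIF targets tested with roxadustat in the libraries labelled retina (liver transcriptome), 24 were higher and none was lower, against 33 higher adjusted over the list alone (adjusted p = 0.153 with an estimated correlation). Pdk1 rose by 1.60 ± 0.22, Higd1a, a mitochondrial protein, by 1.19 ± 0.17 and Slc2a1, a glucose transporter, by 1.44 ± 0.22 on the log2 scale. Of 20 glycolysis genes, 14 were higher (18 adjusted over the list alone), among them Pfkl (1.94 ± 0.27) and Tpi1 (1.20 ± 0.17), also with an adjusted p of 0.153 with an estimated correlation. Exact permutation called both lists, which share genes such as Pgk1 (differences 1.10 and 1.13, adjusted p = 0.0101 each). In the fit without DMOG replicate 5, the HIF targets gave 29 higher and an adjusted p of 6.31e-04 with an estimated correlation, and glycolysis gave 18 higher and 0.00508.

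Of 20 cholesterol synthesis genes, 11 were lower with roxadustat in these libraries and none was higher, among them Srebf2 (-0.57 ± 0.09), Fdft1 (-0.71 ± 0.13) and Idi1 (-0.92 ± 0.17), against 19 lower and 1 higher adjusted over the list alone (adjusted p = 0.161 with an estimated correlation). Of 17 fatty acid synthesis genes, 4 were lower, such as Fasn (-0.88 ± 0.15) and Srebf1 (-0.66 ± 0.15), against 5 adjusted over the list alone (adjusted p = 0.322 with an estimated correlation). Of 17 genes of gluconeogenesis and glycogen, 3 were higher, Igfbp1 (1.69 ± 0.32), Gbe1 (1.09 ± 0.22) and Pck1 (0.94 ± 0.20), also adjusted over the list alone (adjusted p = 0.522 with an estimated correlation). The iron list of 18 gave 2 higher, Epo and Fam132b (1.35 ± 0.26), against 7 adjusted over the list alone (adjusted p = 0.230 with an estimated correlation). Of 29 acute phase genes, 2 were higher, Cebpb (0.84 ± 0.20) and Cebpd (0.71 ± 0.18), against 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.422 with an estimated correlation). Of 14 stellate cell genes, 3 were lower, among them Pdgfrb (-0.33 ± 0.07) and Col1a2 (-0.51 ± 0.13), against 7 lower and 3 higher adjusted over the list alone (adjusted p = 0.233 with an estimated correlation). The cell cycle list was called without a called member (adjusted p = 0.837 with an estimated correlation). By exact permutation of the mean level, cholesterol synthesis (adjusted p = 0.0173), gluconeogenesis and glycogen (0.0101), the iron list (0.0101) and the acute phase list (0.0227) were called. Fatty acid synthesis (0.0559), stellate cells (0.0556) and the cell cycle (0.414) were not. In the fit without DMOG replicate 5, cholesterol synthesis had 17 lower and 1 higher, the iron list 6 higher and the acute phase list 6 higher.

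Further lists were not called by camera with roxadustat in these libraries. The prolyl hydroxylase and HIF pathway had 2 of 8 higher and 2 lower, angiogenic factors and receptors 3 of 26 higher and immediate early genes 3 of 18 higher, with Cdkn1a (2.07 ± 0.28) first. One-carbon metabolism had 2 of 25 higher and 1 lower, the urea cycle 1 of 10 higher, bile acids 1 of 17 lower and drug metabolism 1 of 21 lower. Of 3 exocrine pancreas genes, 1 was higher. Oxidative phosphorylation, the unfolded protein response, the clock, fatty acid oxidation, the interferon response, and the erythroid, neutrophil, macrophage, liver endothelium, bile duct and lymphocyte lists had 0 called members each. By exact permutation, immediate early genes and the prolyl hydroxylase and HIF pathway were called higher (adjusted p = 0.0101 each), and the clock lower (0.0337). In the fit without DMOG replicate 5, immediate early genes had 7 higher and 2 lower and were called as a list at the preset correlation (adjusted p = 0.00743, and 0.228 with an estimated correlation). The pathway of the prolyl hydroxylases then had 3 higher, drug metabolism 2 lower and one-carbon metabolism 2 lower, and the clock, bile duct, liver endothelium and unfolded protein lists had 1 called member each.

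Roxadustat and DMOG, which are different compounds, were also compared directly in the libraries labelled retina (liver transcriptome). Nr0b2 was higher with roxadustat, at 29.3 ± 5.08 FPKM against 5.19 ± 7.92 FPKM with DMOG (mean ± SD, n = 6 per group), a log2 fold change of 3.15 ± 0.45 (SE, adjusted p = 0.00161). Tdo2, a tryptophan-degrading enzyme, was higher by 2.39 ± 0.49 (adjusted p = 0.0169), Lmcd1 by 1.76 ± 0.24, Slc17a4 by 1.63 ± 0.21 and Bmf, a cell death gene, by 1.61 ± 0.20 on the log2 scale. Tnnc1 (-1.51 ± 0.36, adjusted p = 0.0315), Tat, a tyrosine transaminase (-1.21 ± 0.29), Plk3 (-1.21 ± 0.30), Smox, a polyamine oxidase (-1.19 ± 0.22), and Got1, an aspartate transaminase (-1.17 ± 0.23), were lower with roxadustat. In all, 379 genes were called, 235 higher and 144 lower with roxadustat, against 2267 at an unadjusted p under 0.05. Without DMOG replicate 5, 2052 genes were called, 1147 higher and 905 lower, and with each library rescaled to an equal total 83.1% of 575 called genes were higher, against 62.0% here. With the Xist level as a covariate, 70 genes were called. The count fell to 104, 175, 137 and 151 without DMOG replicates 1, 3, 4 and 6, and to 191, 191, 244, 147, 252 and 164 without roxadustat replicates 1 to 6.

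Hypoxia genes were not called between the drugs in the libraries labelled retina (liver transcriptome). Egln1 differed by -0.06 (95% interval -0.43 to 0.30), Vegfa by -0.36 (-0.77 to 0.04), Pdk1 by 0.16 (-0.31 to 0.62) and Epo by -1.21 (-2.68 to 0.25) on the log2 scale, roxadustat minus DMOG. The interval of Egln3, -1.88 to -0.38, lay below 0, though its adjusted p was 0.0923. Without DMOG replicate 5, Egln3 (-1.58 ± 0.13, adjusted p = 1.15e-06), Epo (-2.13 ± 0.19, adjusted p = 2.05e-06) and Vegfa (-0.59 ± 0.10, adjusted p = 5.66e-04) were lower with roxadustat than with DMOG, while Egln1 (-0.26 ± 0.10, adjusted p = 0.0761) was not called. Hif1a (-0.13 ± 0.08), Epas1 (-0.24 ± 0.12), Egln2 (-0.07 ± 0.08) and Hif1an (0.07 ± 0.05) were not called either with all 6 libraries.

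Between roxadustat and DMOG in these libraries, 0 of 36 HIF targets and 0 of 20 glycolysis genes were called, also adjusted over the list alone, while without DMOG replicate 5, 13 HIF targets were lower with roxadustat (adjusted p = 0.293 with an estimated correlation), and 7 glycolysis genes were lower and 1 higher (0.711). Of 17 genes of gluconeogenesis and glycogen, 4 were lower, among them Ppargc1a (-0.94 ± 0.15) and Irs2 (-0.79 ± 0.19), against 6 adjusted over the list alone. Of 10 urea cycle genes, 3 were lower, such as Nags (-1.0003 ± 0.19) and Arg1 (-1.09 ± 0.22), and of 20 cholesterol synthesis genes, 3 were lower, such as Lss (-0.94 ± 0.14) and Idi1 (-0.69 ± 0.17), against 3 and 5 adjusted over the list alone. Ppara (0.65 ± 0.17) was higher in the list of fatty acid oxidation, and Zbtb16 (-0.98 ± 0.20) was lower in that of immediate early and glucocorticoid genes. These 5 lists were called at the preset correlation, and each had an adjusted p of 0.870 with an estimated correlation. Of the lists not called by camera, bile acids had 3 of 17 higher and 1 lower, the iron list 2 of 18 higher, the clock 2 of 13 higher and angiogenic factors 2 of 26 lower. The acute phase list had 1 of 29 higher, fatty acid synthesis 1 of 17 lower, stellate cells 1 of 14 lower and the exocrine pancreas, which was not tested as a list, 1 of 3 higher. The exact permutation test called 0 of 28 lists between the drugs. In the absence of DMOG replicate 5, immediate early genes had 9 lower and 1 higher, gluconeogenesis and glycogen 7 lower, angiogenic factors 6 lower and 1 higher, and fatty acid oxidation 5 higher. The acute phase list then had 4 lower, the iron list 3 lower, the prolyl hydroxylase and HIF pathway 3 lower, and one-carbon metabolism 3 higher and 3 lower. The clock had 3 higher and 2 lower, bile acids 5 higher, the unfolded protein response 2 higher and 2 lower, and drug metabolism 2 higher. The urea cycle had 1 higher beside its 3 lower genes, and the cell cycle 1 lower.

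**Figure D3:**
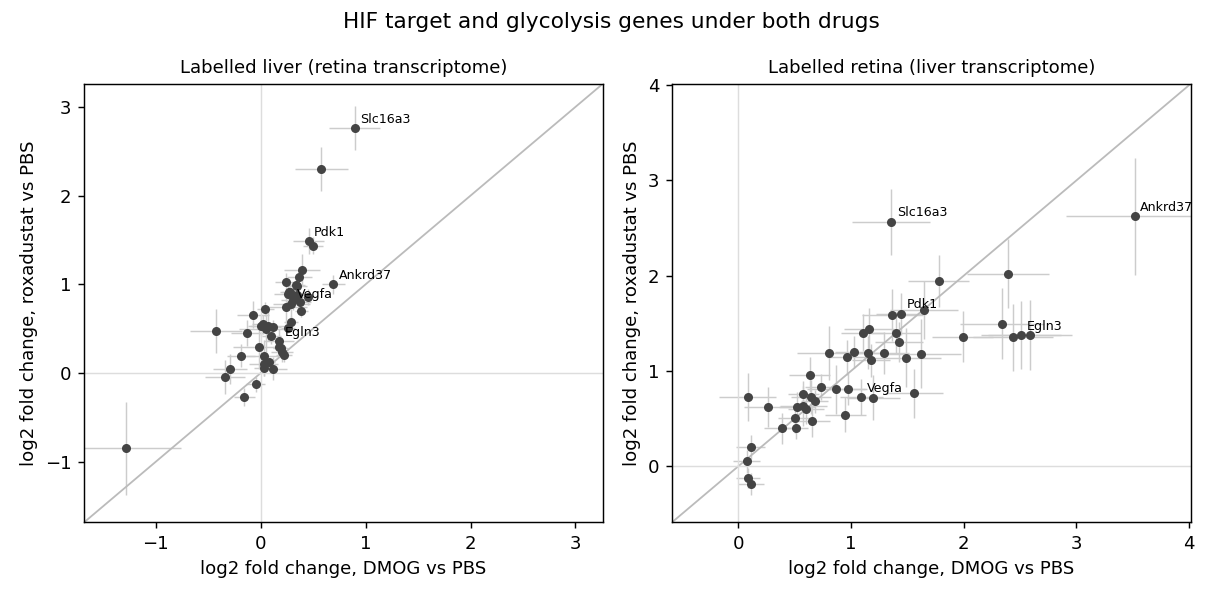
Log2 fold change against PBS of HIF target and glycolysis genes with DMOG (x axis) and with roxadustat (y axis), by tissue label, 1 point per gene reported, with bars for the SE and a line for equality. In the libraries labelled liver (retina transcriptome), Slc16a3 changed by 2.76 with roxadustat, and in the libraries labelled retina (liver transcriptome), Egln3 changed by 2.51 with DMOG and 1.38 with roxadustat.

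The calls of both drugs overlapped in the libraries labelled retina (liver transcriptome). There 373 genes were called in the same direction with both, 203 higher, such as Egln1 and Pdk1, and 170 lower, such as Lars2 and Krt20, and 4 were called in opposite directions. The product of the counts gives 22.6 higher and 29.9 lower by chance. Because both comparisons share the PBS libraries, the overlap was also counted with them divided into separate sets of 3 for each drug. The median was then 93.5 genes (61 to 134). Fewer PBS libraries per comparison also lower the power to call genes, so the fall cannot be put down to shared libraries alone. Simulated unchanged groups gave an overlap of 0, a value that any groups with few called genes give, with or without shared PBS libraries. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.771 with shared PBS libraries and at 0.635 with divided ones. In 100 simulations of unchanged groups the median r was 0.507 and the highest 0.921, so r alone lay within the range without an effect. The covariance was 0.0754, against a simulated median of 0.0104 and a highest of 0.0659. Without DMOG replicate 5 the overlap was 899 genes, and it was 243, 241 and 244 genes without PBS replicate 3, PBS replicate 6 and roxadustat replicate 1. With each library rescaled to an equal total, 30% of 570 overlapping genes were higher, against 54.4% here.

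With roxadustat, hypoxia and glycolysis genes rose in the libraries labelled liver (retina transcriptome). Slc16a3 rose from 8.92 ± 3.78 FPKM with PBS to 60.5 ± 16.1 FPKM with roxadustat (mean ± SD, n = 6 per group), a log2 fold change of 2.76 ± 0.24 (SE, adjusted p = 1.12e-06), higher in 6 of 6 libraries. Dio3, which inactivates thyroid hormone, rose from 2.19 ± 1.43 to 16.3 ± 4.05 FPKM (2.78 ± 0.28, adjusted p = 5.37e-06), and Vegfa from 24.8 ± 6.60 to 42.5 ± 8.66 FPKM (0.78 ± 0.17, adjusted p = 0.0181). Vcam1, an adhesion molecule, fell from 19.0 ± 1.24 to 11.8 ± 1.11 FPKM (-0.67 ± 0.06, adjusted p = 1.33e-06). In all, 323 of 13779 genes were called, 233 higher and 90 lower, against 2409 at an unadjusted p under 0.05. With the lens signal, the mean level of the lens genes, as a covariate, 106 genes were called. Of the 233 higher genes, 89 remained called, and of the 90 lower genes, 4 of them lens list members, 13 did, with standard errors 1.29 times as wide at the median. The count fell to 211 without roxadustat replicate 2 and to 211 without roxadustat replicate 3.

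Further large rises with roxadustat in these libraries were those of Ak4, an adenylate kinase (2.30 ± 0.25, adjusted p = 1.24e-05), Grhpr, a glyoxylate reductase (1.90 ± 0.12, adjusted p = 3.72e-08), Serpine3 (1.76 ± 0.28), Pdk1 (1.48 ± 0.15) and Pfkl (1.44 ± 0.09). S100a8, a gene of neutrophils, rose by 1.25 ± 0.28 (adjusted p = 0.0189), Csn3, a casein, by 1.20 ± 0.12 and Dnahc9, a dynein, by 1.18 ± 0.11 on the log2 scale. Egln1 rose by 0.91 ± 0.07 (adjusted p = 1.17e-07), while Egln3 (0.36 ± 0.14, adjusted p = 0.177), Egln2 (0.15 ± 0.05, adjusted p = 0.144) and Hif1an (0.01 ± 0.05) were not called. Besides Vcam1, the falls included those of Gpd1, which links glycolysis to glycerol (-0.80 ± 0.18, adjusted p = 0.0183), Kcng4, a potassium channel (-0.65 ± 0.16), Rgs6 (-0.61 ± 0.14) and Chrna5, an acetylcholine receptor (-0.51 ± 0.09). Adra2c (-0.49 ± 0.13), Psd2 (-0.49 ± 0.09), Loxl4 (-0.49 ± 0.10) and Col5a3 (-0.48 ± 0.12, adjusted p = 0.0444) followed. Hif1a fell by 0.24 ± 0.05 (adjusted p = 0.0183) on the log2 scale, and Epas1 (-0.18 ± 0.11) was not called.

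Of the 37 HIF targets tested with roxadustat in the libraries labelled liver (retina transcriptome), 21 were higher and none was lower, against 25 higher adjusted over the list alone (adjusted p = 0.0122 with an estimated correlation). Egln1, Ldha, the lactate dehydrogenase gene (0.87 ± 0.06), Kdm3a, a histone demethylase (0.70 ± 0.06), and Pdk1 had the smallest adjusted p. Of 21 glycolysis genes, 15 were higher, among them Pfkl, Ldha, Aldoa (0.99 ± 0.08) and Gpi1 (0.87 ± 0.08), against 17 higher and 1 lower adjusted over the list alone (adjusted p = 0.0232 with an estimated correlation). Both lists were called by exact permutation of the mean level (adjusted p = 0.0202 each). With the lens signal as a covariate, Slc16a3 changed by 2.80 (adjusted p = 9.94e-05), Pdk1 by 1.43 and Egln1 by 0.84, all still called, whereas Vegfa changed by 0.73 (adjusted p = 0.210) and was no longer called.

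The lens list had a median log2 fold change of -3.01 with roxadustat in the libraries labelled liver (retina transcriptome), where the mean lens level of roxadustat replicate 1 (9.16) lay within the PBS libraries (6.80 to 10.20) and that of the other 5 between 3.92 and 6.01. Of its 22 genes, 4 were lower, Mip (-3.78 ± 0.95), Crybb2 (-3.56 ± 0.92), Cryba4 (-3.53 ± 0.87) and Crybb1 (-3.31 ± 0.86), against 20 adjusted over the list alone (adjusted p = 0.243 with an estimated correlation). The prolyl hydroxylase and HIF pathway (2 of 10 higher and 1 lower, 4 and 1 adjusted over the list alone), erythroid cells (1 of 5 higher, Hbb-b1 at 0.89 ± 0.22, 3 adjusted over the list alone) and retinal progenitors (1 of 11 higher, Neurog2 at 0.57 ± 0.13, 5 adjusted over the list alone) were called, each with an adjusted p of 0.219 with an estimated correlation. Immediate early and glucocorticoid genes (0.219), ganglion cells (0.683) and amacrine cells (0.487 with an estimated correlation) were called without a called member. The lists not called by camera included cones, with 3 of 13 higher, Kcne2 (0.58 ± 0.12), Thrb (0.47 ± 0.07) and Opn1sw (0.45 ± 0.09), the clock with 2 of 15 higher, and angiogenic factors with 1 of 27 higher, which was Vegfa. The iron list had 1 of 14 higher, Tfrc (0.51 ± 0.08), pericytes 1 of 9 higher, Ndufa4l2 (1.14 ± 0.20), and the unfolded protein response 1 of 19 higher. Of 4 neutrophil genes, too few for camera, S100a8 was higher. Besides HIF targets and glycolysis, exact permutation called the prolyl hydroxylase and HIF pathway (adjusted p = 0.0202), erythroid cells, progenitors, neutrophils and the unfolded protein response (0.0346 each), and did not call lens (0.0909), immediate early genes (0.0943), ganglion cells (0.409) or amacrine cells (0.194). Oxidative phosphorylation, the cell cycle, the interferon response, rods, bipolar cells, Mueller glia, reactive gliosis, horizontal cells, retinal endothelium, microglia, astrocytes and pigment epithelium had 0 called members each.

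With DMOG, lens genes were lower and a few hypoxia, glycolysis and histone genes were higher in the libraries labelled liver (retina transcriptome). Mip, the gene of a lens water channel, was lower, at 2.87 ± 4.24 FPKM against 279 ± 227 FPKM with PBS (mean ± SD, n = 6 per group), a log2 fold change of -6.48 ± 0.95 (SE, adjusted p = 0.00329). Ankrd37 rose from 21.2 ± 3.50 to 34.4 ± 4.99 FPKM (0.69 ± 0.11, adjusted p = 0.00427), and Hist1h1e, a linker histone gene, from 189 ± 24.2 to 296 ± 29.8 FPKM (0.65 ± 0.09, adjusted p = 0.00329). Vegfa, at 30.2 ± 6.68 FPKM against 24.8 ± 6.60 FPKM (0.29 ± 0.17, adjusted p = 0.457), was not called. In all, 147 of 13779 genes were called, 51 higher and 96 lower, against 1892 at an unadjusted p under 0.05. Of the 96 lower genes, 44 correlated with the lens signal above 0.8 over the 18 libraries. With that signal as a covariate, 1 of the 51 higher genes and 0 of the 96 lower genes, 19 of which are themselves lens list members, remained called. The standard errors were then 1.66 times as wide at the median. Serpine3 went from 1.18 ± 0.28 to 1.39 ± 0.46, Ankrd37 from 0.69 ± 0.11 to 0.57 ± 0.18 and Grhpr from 0.64 ± 0.12 to 0.56 ± 0.20. Ldha went from 0.32 ± 0.06 to 0.20 ± 0.10, Hist1h1e from 0.65 ± 0.09 to 0.50 ± 0.15 and Pfkl from 0.50 ± 0.09 to 0.38 ± 0.15, so the folds of these 3 genes shrank while the errors widened.

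The count of DMOG calls in the libraries labelled liver moved with single libraries. It fell to 78, 63 and 74 without PBS replicates 1, 2 and 6, and to 62, 48, 71 and 61 without DMOG replicates 2, 4, 5 and 6. It rose to 420 without PBS replicate 4 and to 276 without DMOG replicate 3.

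Of called genes with a mean of at least 1 FPKM, the 10 largest falls with DMOG in the libraries labelled liver (retina transcriptome) were all of lens genes, whose products fill the lens fibres. After Mip came the crystallin genes Cryba2 (-6.04 ± 0.93), Cryba1 (-6.03 ± 0.98), Crybb2 (-6.00 ± 0.92) and Crygs (-5.96 ± 0.99), then Lim2, a lens membrane protein (-5.65 ± 0.91), Crygn (-5.64 ± 0.84), Cryba4 (-5.48 ± 0.87), Cryaa (-5.38 ± 0.95, adjusted p = 0.00895) and Crybb1 (-5.09 ± 0.86). Cryaa lay between 1011 and 10054 FPKM in the PBS libraries, between 6.39 and 625 FPKM in the DMOG libraries and between 111 and 5734 FPKM in the roxadustat libraries. Among the largest rises with every DMOG library above the PBS mean were those of Serpine3, a serpin (1.18 ± 0.28, adjusted p = 0.0482), the histone gene Hist1h4j (0.76 ± 0.13, adjusted p = 0.00864), Ankrd37, Cox4i2, a respiratory subunit (0.67 ± 0.16), Hist1h1e, and Grhpr (0.64 ± 0.12). The histone genes Hist1h2be (0.57 ± 0.12), Hist2h4 (0.57 ± 0.12), Hist2h2ac (0.54 ± 0.11) and Hist1h1d (0.53 ± 0.11, adjusted p = 0.0247) followed. Egln1 (0.27 ± 0.07, adjusted p = 0.066), Egln3 (0.17 ± 0.14), Egln2 (0.14 ± 0.05), Hif1an (0.10 ± 0.05), Hif1a (0.04 ± 0.05) and Epas1 (0.01 ± 0.11) were not called.

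**Figure D4:**
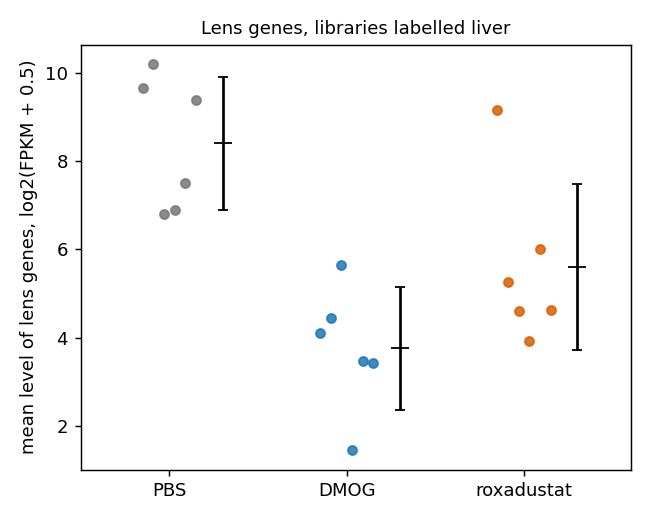
Mean log2(FPKM + 0.5) of the lens genes (y axis) in each library labelled liver (retina transcriptome) by treatment (x axis), 1 point per library, with mean ± SD beside the points (n = 6 per group). The PBS libraries lie between 6.80 and 10.20, the DMOG libraries between 1.45 and 5.65, and the roxadustat libraries between 3.92 and 6.01 with replicate 1 at 9.16.

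Of the 37 HIF targets tested with DMOG in the libraries labelled liver (retina transcriptome), 4 were higher, namely Ankrd37, Ddit4 (0.45 ± 0.09), Kdm3a (0.39 ± 0.06) and Ldha (0.32 ± 0.06), against 11 higher adjusted over the list alone (adjusted p = 0.366 with an estimated correlation). Of 21 glycolysis genes, 5 were higher, with Pfkl (0.50 ± 0.09) and Ldha first, against 11 adjusted over the list alone (adjusted p = 0.281 with an estimated correlation). Of 22 lens genes, 19 were lower, against 22 adjusted over the list alone (adjusted p = 0.150 with an estimated correlation). The exact permutation test called 0 of 28 lists, with an adjusted p of 0.593 for HIF targets, 0.141 for glycolysis and 0.0606 for lens. The lens list had the smallest possible p of this test (0.00216), with 6 of 6 DMOG libraries below every PBS library. A list alone at that p cannot be called after adjustment over 28 lists, so the test could not decide for lens.

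Further lists were called with DMOG in the libraries labelled liver at the preset correlation, with few called members. The iron list (1 of 14 higher, Tfrc at 0.42 ± 0.08), the interferon response (1 of 12 lower) and reactive gliosis (1 of 16 lower, S100a6 at -1.39 ± 0.25) each had an adjusted p of 0.281 with an estimated correlation. Adjusted over the list alone, they had 1 higher and 3 lower, 4 lower, and 1 higher and 1 lower. The prolyl hydroxylase and HIF pathway (10 genes, adjusted p = 0.180 with an estimated correlation), oxidative phosphorylation (29 genes, 0.390), erythroid cells (5 genes, 0.281), the cell cycle (26 genes, 0.587), immediate early genes (17 genes, 0.281), ganglion cells (16 genes, 0.602) and pigment epithelium (14 genes, 0.590) were called without a called member. Rods (20 genes), cones (13), bipolar cells (15), Mueller glia (15), amacrine cells (15) and horizontal cells (7) had 0 called members and were not called. The same held for retinal endothelium (21), pericytes (9), microglia (16), astrocytes (7), progenitors (11), angiogenic factors (27), the unfolded protein response (19), the clock (15) and the untested neutrophil list (4).

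Roxadustat and DMOG differed in the hypoxia genes of the libraries labelled liver (retina transcriptome). Slc16a3 was higher with roxadustat, at 60.5 ± 16.1 FPKM against 16.2 ± 4.62 FPKM with DMOG (mean ± SD, n = 6 per group), a log2 fold change of 1.87 ± 0.24 (SE, adjusted p = 2.02e-04). Dio3 was higher by 3.23 ± 0.28 (adjusted p = 2.3e-06), Cox8b, a respiratory subunit, by 1.73 ± 0.25, Ak4 by 1.72 ± 0.25, Dnahc9 by 1.26 ± 0.11 and Egln1 by 0.64 ± 0.07 (adjusted p = 1.94e-05) on the log2 scale. Vcam1 (-0.57 ± 0.06, adjusted p = 2.13e-05), Lrp4 (-0.57 ± 0.11), Col5a3 (-0.55 ± 0.12), Sema7a, a semaphorin (-0.54 ± 0.07), Nipal1 (-0.53 ± 0.09) and Hif1a (-0.28 ± 0.05, adjusted p = 0.00842) were lower with roxadustat. Vegfa differed by 0.49 (95% interval 0.13 to 0.85) but its adjusted p was 0.253. Egln3 differed by 0.19 (-0.10 to 0.48), Egln2 by 0.01 (-0.10 to 0.13), Hif1an by -0.09 (-0.19 to 0.02) and Epas1 by -0.19 (-0.42 to 0.05), and none of these 4 was called. In all, 181 genes were called, 135 higher and 46 lower with roxadustat, against 1503 at an unadjusted p under 0.05. With the lens signal as a covariate, 95 of the 135 higher and 20 of the 46 lower genes remained called.

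Of the 37 HIF targets, 15 were higher with roxadustat than with DMOG in the libraries labelled liver (retina transcriptome), among them Egln1, Ldha (0.55 ± 0.06) and Pgk1 (0.78 ± 0.11), against 22 adjusted over the list alone (adjusted p = 0.0155 with an estimated correlation). Of 21 glycolysis genes, 13 were higher, such as Pfkl (0.94 ± 0.09) and Aldoa (0.65 ± 0.08), against 17 adjusted over the list alone (adjusted p = 0.0303 with an estimated correlation). Exact permutation called both lists (adjusted p = 0.0121 each).

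The other lists called between the drugs in the libraries labelled liver at the preset correlation held few called genes. They were angiogenic factors with Fgf2 (0.78 ± 0.15) and Thbs1 (0.76 ± 0.18) higher, the iron list with Id1 (0.38 ± 0.08), the cell cycle with Plk1 (0.34 ± 0.08), reactive gliosis with Fgf2, and, without a called member, lens, pigment epithelium, astrocytes, progenitors, pericytes, bipolar cells and oxidative phosphorylation. With an estimated correlation their adjusted p lay between 0.213 for oxidative phosphorylation and 0.278 for pericytes. Exact permutation called angiogenic factors, the iron list and reactive gliosis (adjusted p = 0.0121 each), astrocytes and oxidative phosphorylation (0.026 each), pericytes and, beyond those of camera, the unfolded protein response (0.0404 each). It did not call the cell cycle, lens, pigment epithelium, progenitors or bipolar cells (0.106 to 0.114). Of the lists not called by camera, cones had Thrb (0.43 ± 0.07) higher and the prolyl hydroxylase and HIF pathway had Egln1 higher and Hif1a lower.

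The calls of both drugs overlapped in the libraries labelled liver (retina transcriptome) by 43 genes in the same direction, 30 higher, such as Ankrd37, Grhpr and Pfkl, and 13 lower, such as Mip and Crybb2, with 1 gene called in opposite directions. The product of the counts gives 0.862 higher and 0.627 lower by chance. PBS libraries divided into separate sets for each drug gave a median of 5 genes (0 to 27). The simulated overlap of unchanged groups was 0, a value that any groups with few called genes give. Across genes the log2 fold changes correlated at r = 0.769, and at 0.564 with divided PBS libraries. In 100 simulations of unchanged groups the median r was 0.499 and the highest 0.916, above the value observed. The covariance was 0.0493, against a simulated median of 0.00651 and a highest of 0.0261. With the lens signal as a covariate, the overlap was 1 gene. It was 26, 22, 124, 67 and 28 genes without PBS replicates 1, 2, 4, 5 and 6, 23, 25, 22 and 21 without DMOG replicates 2, 4, 5 and 6, and 82, 24 and 25 without roxadustat replicates 1, 2 and 5.

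The response of Egln3, Egln1 and Vegfa to DMOG differed between the tissue labels. The response of Egln3 was lower in the libraries labelled liver (retina transcriptome), where it was not called, than in those labelled retina (liver transcriptome). The difference of log2 fold changes was -2.33 ± 0.39 (SE, n = 6 per group, adjusted p = 3.08e-04), labelled liver minus labelled retina. Egln1 differed by -0.91 ± 0.19 (adjusted p = 0.00152) and Vegfa by -0.80 ± 0.27 (adjusted p = 0.038) in the same direction. Crybb3 (-7.30 ± 1.02), Nupr1, a stress-response regulator (-5.15 ± 0.79), Tmem40 (-3.40 ± 0.65) and Cryab, a small heat shock protein (-3.38 ± 0.69, adjusted p = 0.00136), were among the most negative differences. Bex2 (1.98 ± 0.48), Arsg (1.51 ± 0.33), Chka, a choline kinase (1.51 ± 0.30), Hlf (1.45 ± 0.26) and Gldc, of glycine cleavage (1.43 ± 0.30, adjusted p = 0.00172), were among the most positive. Epas1 (0.21 ± 0.17), Hif1a (0.22 ± 0.09, adjusted p = 0.101), Egln2 (0.24 ± 0.09, adjusted p = 0.0742) and Hif1an (0.17 ± 0.07, adjusted p = 0.0864) were not called, though without DMOG replicate 5 of the libraries labelled retina Hif1a (0.27 ± 0.09, adjusted p = 0.021) and Egln2 (0.26 ± 0.10, adjusted p = 0.0415) were. The crystallin differences include the lens signal of the libraries labelled liver. Nupr1 went there from 122 ± 83.9 FPKM with PBS to 5.18 ± 8.57 FPKM with DMOG (mean ± SD). Tmem40 went from 9.68 ± 7.09 to 0.415 ± 0.419 FPKM. Both were among the 96 genes lower with DMOG in that label, of which 0 remained called with the lens signal as a covariate. The differences between labels were not fitted with that covariate, so the lens share in them cannot be told. In all, 1763 of 11101 genes differed, 989 positive and 774 negative, and without DMOG replicate 5 of the libraries labelled retina 3202 did. With each library rescaled to an equal total, 77.4% of the differences were positive, against 56.1% here.

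For roxadustat, Egln1, Vegfa and Egln3 were not called different between the tissue labels with all libraries. Egln1 differed by -0.21 ± 0.19 (SE, n = 6 per group, adjusted p = 0.640), Vegfa by 0.05 ± 0.27 (adjusted p = 0.952) and Egln3 by -1.01 ± 0.39 (adjusted p = 0.183). Egln2 (0.33 ± 0.09, adjusted p = 0.0533), Hif1an (0.02 ± 0.07), Hif1a (0.07 ± 0.09) and Epas1 (0.26 ± 0.17) were not called either. In the fit without DMOG replicate 5 of the libraries labelled retina, Egln3 (-1.01 ± 0.19, adjusted p = 9.41e-04) and Egln2 (0.33 ± 0.09, adjusted p = 0.0355) were called. Grhpr (1.77 ± 0.18, adjusted p = 2.52e-07), Dio3os, next to Dio3 (1.77 ± 0.37), Ak4 (1.57 ± 0.32), Igfbp3, a carrier of growth factors (1.21 ± 0.32), and Sc4mol (1.14 ± 0.27) were among the most positive differences. Crybb3 (-5.74 ± 1.02), S100a4 (-2.01 ± 0.52), Cdkn1a (-2.004 ± 0.31) and A2m (-1.98 ± 0.54, adjusted p = 0.0434) were among the most negative. These differences were not fitted with the lens signal as a covariate. In all, 249 of 11101 genes differed, 114 positive and 135 negative. The count was 160 without roxadustat replicate 2 of the libraries labelled liver and 527 in the fit without DMOG replicate 5 of the libraries labelled retina. With each library rescaled to an equal total, 58.8% of the differences were positive, against 45.8% here.

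Genes called in both tissue labels in the same direction numbered 22 for DMOG, 13 higher and 9 lower, against 3.38 and 6.55 by chance, and 65 for roxadustat, 60 higher and 5 lower, against 4.23 and 1.17 by chance. Ankrd37, Pfkl and Aldoa, picked after their values were seen, were among those higher with both drugs in both labels. For DMOG 2 genes and for roxadustat 1 gene had calls in opposite directions.

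**Figure D5:**
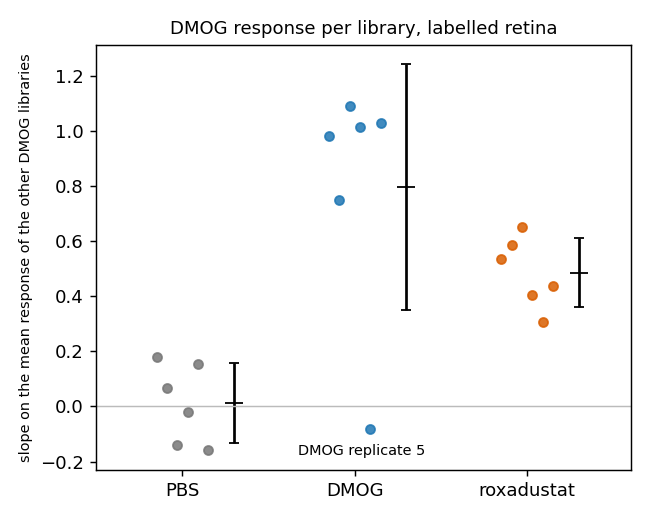
Slope of each library's deviation from the PBS mean on the mean response of the other DMOG libraries (y axis) by treatment (x axis) in the libraries labelled retina (liver transcriptome), 1 point per library, with mean ± SD beside the points. DMOG replicate 5 is at -0.0825, within the PBS libraries at -0.159 to 0.180, and the other 5 DMOG libraries are at 0.748 to 1.09.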

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

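The tests of the tissue labels, and those of DMOG replicate 5 of the libraries labelled retina as exchanged with a PBS or roxadustat library or as a PBS library, were chosen after the result was seen. A library was singled out where its gap to the nearest other library, divided by the range of its group, exceeded the 95% critical value of Dixon's test. This held in 48 of 396 groups, and chance gives about 1 in 20 groups.

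The first pattern is the disagreement between tissue labels and transcriptomes. All 36 libraries had the higher mean level for the lists of the other tissue, and the rod genes of the libraries labelled retina reached at most 0.0401% of their sum in the other table, which argues against RNA of both tissues mixed in each library. Whether tables or labels were exchanged as a whole stays open. No biological explanation was tested.

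The second pattern is DMOG replicate 5 of the libraries labelled retina (liver transcriptome), which was lowest of its group for Bnip3 (gap over range 0.729), Egln3 (0.792), Epo (0.910), Ero1l (0.762), Fam162a (0.767), O3far1 (0.887), P4ha2 (0.758), Vegfa (0.746). It was also lowest for the mean levels of the HIF targets (0.758), the prolyl hydroxylase and HIF pathway (0.633), glycolysis (0.837), the iron list (0.668) and immediate early genes (0.805). It was highest for Krt20 (0.643), Mid1ip1 (0.766) and Osgin1 (0.645). On the response of the other DMOG libraries its slope was -0.0825, no PBS library lay above 0.180, and the lowest roxadustat library was at 0.306, so no PBS library lay with DMOG and this one not with roxadustat, which argues against an exchange with either. Its relative depth of 0.976 lay within that of the other 17 libraries (0.723 to 1.20), and a PBS library under a DMOG label or an animal without the drug stays open, with no biological explanation tested.

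The third pattern is the lower level of lens genes with DMOG in the libraries labelled liver (retina transcriptome). Over deviations from the group means, 7 other lens genes and 15 crystallins correlated at r = 0.941 (two-sided permutation p = 1e-05, n = 18), and with the other lens genes as a covariate the median log2 change of the crystallins went from -5.03 to -0.37 (-1.18 to 1.49), which argues against a crystallin response of retinal cells. Lens tissue carried along in the dissection stays open, as does an effect of the drug on the lens or on how it parts from the retina, which was not tested. With the lens list as a covariate, Hist1h1e, which is not a lens gene, went from 0.65 ± 0.09 to 0.50 ± 0.15, and its call ended (adjusted p = 0.999 by limma) as the error widened and the fold shrank.

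In the other libraries labelled liver (retina transcriptome), PBS replicate 5 was lowest for Serpine3 (0.634), and PBS replicate 1 was highest for the interferon response (0.678) and ganglion cells (0.667) and lowest for cones (0.783). DMOG replicate 1 was highest for Ak4 (0.792), Dnahc9 (0.723) and rods (0.715) and lowest for Hist1h4j (0.724), Hist2h4 (0.749) and retinal progenitors (0.675). DMOG replicate 2 was lowest for Grhpr (0.697), angiogenic factors (0.682), retinal endothelium (0.753) and pericytes (0.680), DMOG replicate 4 for Hif1a (0.651) and DMOG replicate 5 for Hif1an (0.700). Roxadustat replicate 1 was highest for Gpd1 (0.666) and lowest for microglia (0.679), and roxadustat replicate 6 was highest for Loxl4 (0.789).

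Among the libraries labelled retina (liver transcriptome), PBS replicate 3 was lowest for Ero1l (0.726), PBS replicate 5 for the iron list (0.636) and gluconeogenesis and glycogen (0.731), and PBS replicate 1 was highest for macrophages (0.653). DMOG replicate 6 was highest for Hif1an (0.680). Roxadustat replicate 2 was highest for A2m (0.632) and lowest for Ankrd37 (0.717), Epo (0.884) and O3far1 (0.833). Roxadustat replicate 5 was highest for Clec2h (0.626) and Nr0b2 (0.717), and roxadustat replicate 4 was lowest for Slc34a2 (0.725).

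The response to DMOG differed between the labels in 1763 genes by the test of the difference itself. Among the genes named, the differences were 1.98 for Bex2, 1.51 for Arsg, 1.51 for Chka, 1.45 for Hlf, 1.43 for Gldc, -7.30 for Crybb3, -5.15 for Nupr1, -3.40 for Tmem40, -3.38 for Cryab. They were -0.91 for Egln1, -2.33 for Egln3 and -0.80 for Vegfa on the log2 scale. For roxadustat 249 genes differed, with 1.77 for Grhpr, 1.77 for Dio3os, 1.57 for Ak4, 1.21 for Igfbp3, 1.14 for Sc4mol. Among the lowest were -5.74 for Crybb3, -2.01 for S100a4, -2.004 for Cdkn1a and -1.98 for A2m. DMOG replicate 5 of the libraries labelled retina moves these counts, to 3202 for DMOG without it and to 527 for roxadustat in the fit without it, and roxadustat was at 160 without roxadustat replicate 2 of the libraries labelled liver. The differences between labels were not fitted with the lens signal as a covariate.

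Each count was set against 100 splits of the same libraries, the real one included. For the label liver, 3 of 100 splits gave as many genes as DMOG against PBS (147 genes, highest other 275). There 1 of 100 gave as many as roxadustat against PBS (323, highest other 321), 1 of 100 as many as roxadustat against DMOG (181, highest other 0) and 1 of 100 as large an overlap (43, highest other 0). For the label retina, 1 of 100 splits gave as many for DMOG (2526, highest other 1), for roxadustat (530, highest other 0), for roxadustat against DMOG (379, highest other 3) and for the overlap (373, highest other 0). For the difference between labels it was 1 of 100 for DMOG (1763, highest other 305) and 1 of 100 for roxadustat (249, highest other 3). The share was under 0.05, the limit set beforehand, for each of the 8 counts of genes, without adjustment over the counts. For DMOG against PBS with the label liver, another split gave 275 genes against 147. Chance is therefore not excluded for that count, while for the other counts of genes no other split gave as many. The overlaps add nothing to these shares, since an overlap needs genes called for both drugs. In the splits of single comparisons, at most 7 of the other 99 had any gene called for a drug against PBS. The overlaps were counted on separate splits of all 18 libraries, for which the calls of each drug were not recorded.

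Chance is not excluded for the counts of lists called at the preset correlation. With the label liver, 26 of 100 splits gave as many lists for DMOG (13 lists, highest other 18), 49 of 100 for roxadustat (9, highest other 17) and 15 of 100 for roxadustat against DMOG (13, highest other 18). With the label retina, 14 of 100 did for DMOG (13, highest other 15), 39 of 100 for roxadustat (9, highest other 16) and 94 of 100 for roxadustat against DMOG (5, highest other 17).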

How the results depend on the processing

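The lens covariate and the fit without DMOG replicate 5 were chosen after the data were seen, and the cause of a change was not tested unless stated. Of 422 counts under alternatives, 334 stayed within 1.5 times the count reported and 88 did not. Of 18871 values of named genes 17772 kept their direction and side of the threshold, 776 lost the call, 323 gained one and 0 reversed. Names give the label of the libraries, and shared genes are those also called in the fit reported. With no filter, liver DMOG lists were 8 (8 shared), the liver overlap 28 (22), retina roxadustat against DMOG 232 (219) and the roxadustat difference between labels 394 (243). At a mean of at least 5 FPKM, with fewer genes tested, liver DMOG lists were 7, retina DMOG 1655 (1613 shared), retina roxadustat 325 (320) and retina lists of roxadustat against DMOG 3. The retina overlap was 244 (240), and the differences between labels 976 (952) for DMOG and 113 (113) for roxadustat. Rescaled to an equal total, retina roxadustat against DMOG was 575 (325 shared), its lists 8 and the retina overlap 570 (333). With array weights, liver DMOG, roxadustat and roxadustat against DMOG were 551 (147 shared), 512 (315) and 607 (181) and the overlap 119 (42). The retina counts were 4240 (2504), 1590 (530) and 1692 (379) and the overlap 1163 (372). The differences between labels were 3191 (1742) and 737 (247). With an estimated correlation, lists were 0, 2 and 2 in liver and 0, 0 and 0 in retina. With the 2 groups alone, liver DMOG was 94 (87 shared), liver roxadustat 190 (186), retina roxadustat 1229 (528) and retina roxadustat against DMOG 62 (62). With Xist as a covariate retina roxadustat against DMOG was 70 (67 shared). With the lens covariate, liver DMOG was 1, its lists 8, liver roxadustat 106 (102 shared) and the liver overlap 1 (0). Without DMOG replicate 5 in the fit, retina roxadustat was 1111 (530 shared) and the roxadustat difference 527 (249). With 1 library of the groups compared left out in turn, liver DMOG ranged from 48 to 420 (DMOG replicate 4, PBS replicate 4), and liver roxadustat from 211 to 481 (roxadustat replicate 2, PBS replicate 4). Liver roxadustat against DMOG ranged from 128 to 214 and the liver overlap from 21 to 124 (DMOG replicate 6, PBS replicate 4). Retina DMOG ranged from 1809 to 4489 (DMOG replicates 4 and 5), retina roxadustat from 344 to 507 and retina roxadustat against DMOG from 104 to 2052 (DMOG replicates 1 and 5). The retina overlap ranged from 241 to 899 (PBS replicate 6, DMOG replicate 5), and the differences between labels from 1385 to 3202 and from 160 to 299. Lists ranged from 10 to 17, 7 to 13 and 13 to 17 in liver and from 8 to 15, 8 to 13 and 2 to 10 in retina. Pseudocounts, the median ratio, no mean trend, robust empirical Bayes and separate fits of the tissues left each count they were run for within 1.5 times. Robust empirical Bayes was not run for lists. With the replicate number as a block, the counts were 138, 340 and 175 with an overlap of 53 in liver, 2843, 539 and 396 with an overlap of 373 in retina. They were 2097 and 297 for the differences, with lists of 12, 7 and 13 and of 12, 9 and 4. Pairing of the libraries by number was not clear and is not excluded. The deviations of libraries with the same number correlated between -0.333 and 0.546. In liver 4 of 18 libraries and in retina 7 of 18 correlated best with their own number. Each was set against the libraries of the other 2 treatments, where 1 of 6 per treatment carries its number, and no test against chance was made. Read depth is unknown without counts, so no limit of detection is given.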

Other observations

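The histone and dioxygenase lists were chosen after their values were seen. Of 56 histone genes in the libraries labelled liver (retina transcriptome), 12 were higher with DMOG (median log2 fold change 0.47) and 18 with roxadustat (0.54), and none of the 56 was lower with either drug. Hist1h1c rose by 0.48 with DMOG and 0.41 with roxadustat, and Hist1h2an by 1.14 with roxadustat. In the libraries labelled retina (liver transcriptome), 1 of 58 histone genes was lower with DMOG, Hist2h2be (-0.86), and 1 was higher with roxadustat, Hist1h2bk (0.82), while the medians were 0.24 and 0.26, with 50 and 54 of 58 above 0. With the lens covariate, 0 histone genes were called higher with DMOG and 3 with roxadustat in the libraries labelled liver, by limma, with medians of 0.42 and 0.48 and a median standard error that went from 0.15 to 0.25 for DMOG and to 0.19 for roxadustat.

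Both drugs act on enzymes that use 2-oxoglutarate. The list taken here holds 47 dioxygenases of this family and leaves out Egln1 and Egln3, which belong to it. Of the 47 listed, 4 (P4ha1, P4ha2, Plod2 and Kdm3a) are also among the HIF targets. In the libraries labelled retina (liver transcriptome), 14 of 44 were higher with DMOG, such as P4ha2 (2.44), Alkbh5 (0.86) and Kdm4b (0.72). Lower were 2, Alkbh7 (-0.48) and Bbox1 (-0.57). The median member went from 0.16 to 0.08 when rescaled to an equal total and to 0.15 by the median ratio. With roxadustat 8 of 44 were higher, such as Kdm3a (0.83) and Alkbh5 (0.80). The median member went from 0.03 to -0.01 when rescaled to an equal total and stayed at 0.03 by the median ratio. With the label liver (retina transcriptome), 1 of 45 was higher with DMOG, Kdm3a (0.39), and 7 of 45 with roxadustat, such as Kdm3a (0.70) and Jmjd6 (0.57).

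The mean level of the lens genes in the libraries labelled liver was lower by 4.65 with DMOG on the log2 scale (-4.65, two-sided exact permutation p = 0.00216, adjusted p = 0.0606) and by 2.81 with roxadustat (-2.81, exact permutation p = 0.0260, adjusted p = 0.0909). Inferred sexes agreed between the labels for 6 of 18 replicate numbers.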
